A study of Drosophila melanogaster with 4 samples.

How the data were processed

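The assay was chromatin immunoprecipitation followed by sequencing of formaldehyde-crosslinked whole embryos of wild-type Drosophila melanogaster (strain Oregon-R), labelled 14 to 16 h of development. The antibody was raised against dimethylated lysine 79 of histone H3 (H3K79me2). The labels give 2 groups of 2 samples each: 2 immunoprecipitated (ChIP) samples and 2 input samples, which are chromatin not taken through the antibody step. Files were listed for the 2 ChIP samples and for the series as a whole. The input samples are not analysed here on their own. Per the labels, input replicate 1 served ChIP replicate 2, and input replicate 2 served ChIP replicate 1. Nothing in the labels says whether the replicates came from separate embryo collections, so the spread between them may be technical.

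Each of the 3 deposited files is a list of regions that the authors called significantly enriched, with 1-based start and end on FlyBase release 5 of the genome, per the file headers. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The region caller, its threshold, its window and the way the replicates were combined are not given in the sources used here. Each region carries 1 score, deposited by the authors in the score column of the file, per the file headers in no stated unit. The 2 regions called depleted have scores just below 0. The score is therefore treated as a value with no fixed scale. It is used to rank regions, to sort them into classes, and to compare regions or their medians within and between lists. Comparisons are by differences and never by folds. The class limits of 1 and 2 are the same for both replicates, although scores were lower in replicate 2. Enriched and depleted regions were separated by the source label of each line.

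Read numbers and sequencing depth are unknown, since the lists hold no counts. A region missing from a list can therefore not be told from one that the depth could not reach, and no counting interval for enrichment can be given. Wilson intervals are given for shares of regions, at 95% confidence, and cover counting error only. Differences between replicates in number, width or score of regions can come from depth as well as from the chromatin.

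The reference table at hand is of assembly release 6 and the files use release 5. Coordinates were not converted and no gene was named from a position. Of the analyses fixed before the data were examined, the 5 that need a release 5 annotation were not run: gene features, the profile around transcription start sites, the marked genes, 21 fixed gene lists and gene length. All 21 gene lists therefore have no result here. Regions are named by coordinates, by a rule fixed at the same time: the 10 widest and the 10 highest-scoring regions of the list for the replicate set that both replicate lists cover by at least 50%, with the Het sequences and U counted apart. The Het sequences are release 5 scaffolds assigned to the heterochromatin of a chromosome, U collects unplaced scaffolds, and Uextra, which carries no region in any list, was left out of all lengths.

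Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Values per replicate list were averaged as mean ± SD (n = 2). With 2 samples of 1 group and no values for the input group, no test between groups exists. Overlap between the replicate lists was tested against 1000 circular shifts of one list within each sequence (one-sided permutation test). The alternatives of this test used 200 shifts, for which 0.005 is the smallest p. Spacing of regions was tested against 1000 random placements of the same regions on each arm without overlap (one-sided). Differences between X and the autosomal arms carry 95% bootstrap intervals over 500 kb blocks, and other medians 95% bootstrap intervals over regions, each from 2000 draws. Only whole blocks entered the intervals for X, whereas the differences themselves use whole arms. The part of X left out, from 22000001 to its end, was covered to 3.76% in each replicate. Regions that overlapped exactly 1 region of the other list, and were its only partner, were paired one to one. Sets of paired regions were compared with 10000 random sets of arm regions, drawn with replacement and matched on deciles of mean score and width. Regions are not replicates, so these comparisons describe these 2 libraries. The code was tested on simulated data: of the 5090 regions of replicate 1, 80% were kept in a simulated list and 80.5% were recovered as shared, and 0 of 20 pairs of independent lists passed the threshold of 0.05.

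Alternatives fixed before the data were examined were the higher-scoring 50% of each list, regions of at least 1000 bp, merging of regions less than 500 bp apart, the 5 large arms only, the list for the replicate set, each replicate alone, and other overlap limits. Analyses of arm ends, spacing, score classes, sharing by sequence and score differences between replicates were added after the data had been seen.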

Results

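The data describe where dimethylation of histone H3 at lysine 79 was enriched over input chromatin in late Drosophila embryos. H3K79me2 is deposited by the Dot1 family methyltransferase, grappa in the fly, and lies over transcribed genes, mainly in their 5′ part. The 2 ChIP replicates each had a list of enriched regions, and a further list covered the replicate set. Replicate 1 had 5090 enriched regions and replicate 2 had 5061. The list for the replicate set had 5314. Sequencing depth is unknown, and values from the input samples are not analysed here apart from their role in the authors' calls.

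How much of the genome carried the mark was the first question. H3K79me2 occupied many short domains that together covered 12.7% ± 1.20 (SD, n = 2) of the 139.7 Mb of sequence with at least 1 region. Covered length was 16.6 Mb in replicate 1 and 19.0 Mb in replicate 2. Domains had a median width of 2979 bp ± 208 (SD, n = 2), with lower and upper quartiles of 2426 and 4110 bp as means of the replicates. The narrowest regions measured 1301 bp in replicate 1 and 1302 bp in replicate 2. Domains of at least 5 kb made up 10.6% of regions in replicate 1 and 19.0% in replicate 2. The number of regions differed little between replicates (5076 ± 20.5, SD, n = 2), whereas replicate 2 had wider regions with lower scores. Its median width was 3126 bp against 2832 bp, and its median score was 1.87 against 2.19. Over 4286 regions paired one to one, the median width was larger in replicate 2 by 299.5 bp (95% bootstrap interval 285.5 to 311), and 84.7% of pairs were wider in replicate 2.

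The widest domains of the replicate set that both replicates covered lay on 2L (5 of 10), X (4) and 2R (1), in FlyBase release 5 coordinates. The widest spanned 18.7 kb on 2L from 4964790 to 4983498, with a score of 2.91. Replicate 2 held this domain as a single region of 18.7 kb, and replicate 1 held it as 2 regions, the larger of 13.8 kb. An 18.2 kb domain on 2R from 8054554 to 8072728 scored 2.74, and was likewise 1 region in replicate 2 and 2 in replicate 1. On X, a 17.0 kb domain from 508838 to 525858 was 1 region in each replicate, of 16.3 kb in replicate 1 and 17.2 kb in replicate 2. On 2L, a 16.9 kb domain from 11986232 to 12003164 had nearly the same width in replicate 1 (16.8 kb) and replicate 2 (16.9 kb), with scores of 2.85 and 2.75. A pair of wide domains stood next to each other on X, from 11462116 to 11476518 (14.4 kb, score 2.66) and from 11480442 to 11495678 (15.2 kb, score 2.06). The 10 widest domains ranged from 13.4 to 18.7 kb and scored 2.06 to 2.91, below the highest scores.

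The 10 highest-scoring domains were narrower, from 3.52 to 7.47 kb, and lay on X (4), 3L (3), 2R (2) and 2L (1). The highest score, 3.55, belonged to a 4.12 kb domain on X from 6187360 to 6191482, which scored 3.75 in replicate 1 and 3.44 in replicate 2. A 5.12 kb domain on 2L from 8040204 to 8045324 scored 3.52 in the replicate set, 3.97 in replicate 1 and 2.93 in replicate 2. A 4.13 kb domain on 3L from 20800560 to 20804690 scored 3.51, and a 4.17 kb domain on 2R from 19433492 to 19437658 scored 3.49. On X, the domain from 19371704 to 19376626 had the most similar scores of the 10, 3.50 in replicate 1 and 3.54 in replicate 2. No domain of either list of 10 lay on 3R or on chromosome 4. Across all regions, wider regions scored higher: Spearman's rho between width and score was 0.73 in replicate 1 and 0.70 in replicate 2, across regions, which are not independent replicates.

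Whether the replicates marked the same places was asked next. They did so for most of their length: 15.7 Mb was shared, which was 94.4% of the covered base pairs of replicate 1 and 82.6% of those of replicate 2. The Jaccard index of covered base pairs was 78.7%, against 7.80% ± 0.31 (SD over 1000 circular shifts). None of the shifts reached the observed overlap (one-sided permutation p = 0.001, the smallest these shifts can give). At least 50% of their length was covered by the other replicate for 4818 regions (94.7%) of replicate 1 and 4583 (90.6%) of replicate 2, against shift means of 15.5% and 13.1%. In replicate 1 this share was 95.1% on the large arms. It was lower on chromosome 4 (77.2% of 57 regions, 95% Wilson interval 64.8% to 86.2%) and on the Het sequences and U (81.6% of 76, 71.4% to 88.7%). In replicate 2 the shares were 90.6%, 87.3% (76.0% to 93.7%) and 87.5% (77.9% to 93.3%). Scores of paired regions had a Spearman correlation of 0.86 and a Pearson correlation of 0.87 across 4286 regions. Their widths had a Spearman correlation of 0.89.

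Sharing depended on the score, counting a region as shared where at least 50% of it was covered. Regions scoring 2 or more were covered by the other replicate in 99.9% of 2807 cases in replicate 1 (95% Wilson interval 99.7% to 100.0%) and in 99.8% of 2242 cases in replicate 2 (99.5% to 99.9%). Regions scoring under 1 were covered in 79.4% of 1161 cases in replicate 1 (77.0% to 81.6%) and in 65.5% of 1248 cases in replicate 2 (62.8% to 68.1%). These low-scoring regions made up 22.8% of regions and 14.4% of covered length in replicate 1, and 24.7% of regions and 14.4% of covered length in replicate 2. In replicate 1, 253 regions had no overlap with replicate 2, and their median score was 0.52 against 2.28 for regions with a partner. In replicate 2, 420 regions had no partner, with a median score of 0.53, against 1.965 for regions with a partner.

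**Figure D1:**
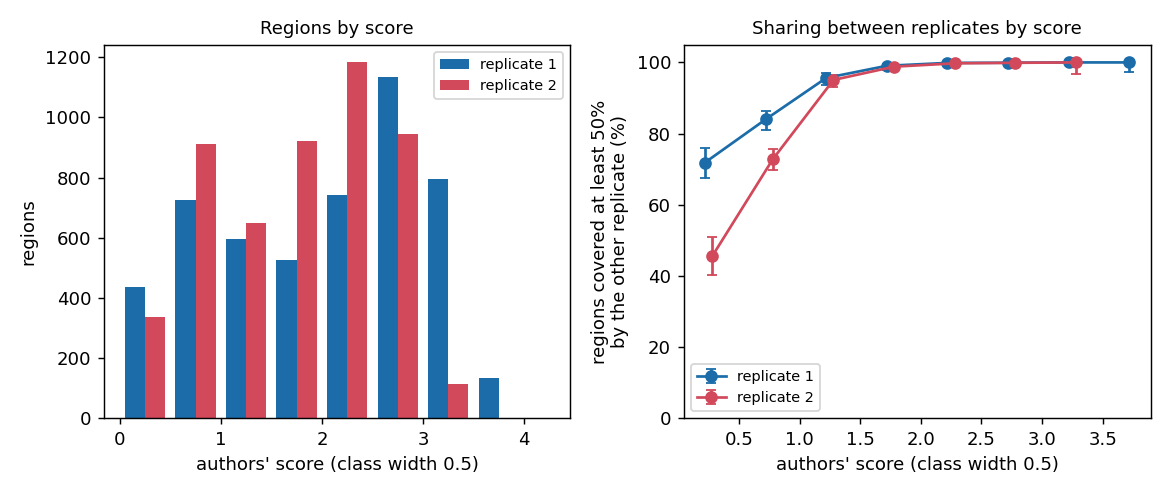
Left, number of enriched regions in each replicate by the authors' score in classes of 0.5; right, share of regions covered at least 50% by the other replicate, with 95% Wilson intervals, for classes of at least 20 regions. Sharing rises from 71.9% in replicate 1 and 45.5% in replicate 2 for scores under 0.5 to over 99% for scores of 2 and more.

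The list for the replicate set was compared with the single lists. Of its covered length, 82.9% lay in both replicates, 4.37% in replicate 1 only, 11.7% in replicate 2 only and 1.00% in neither. Both replicates covered at least 50% of 4649 of its 5314 regions. Only replicate 1 did so for 242 regions and only replicate 2 for 325. A further 97 regions touched neither replicate list, with a median score of 0.32 and a median width of 1229 bp, against 2.14 and 3271 bp for the regions that both replicates covered. The narrowest region of the list for the replicate set measured 1001 bp, against 1301 and 1302 bp in the replicate lists. The median of 1229 bp lay below both of these, so low score and a different lower limit of width were not told apart.

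The chromosomes carried the mark unequally. Arm 2R had the highest covered share among the large arms, 16.8% ± 1.61 (SD, n = 2), and 2L the lowest, 13.2% ± 1.08, with 48.5 and 38.0 regions per Mb. Replicate 1 gave 15.7% for 2R and 12.5% for 2L, and replicate 2 gave 18.0% and 14.0%, so the order held in both. Arms 3L and 3R were covered to 13.9% ± 1.22 and 14.8% ± 1.56. Chromosome 4, a small chromosome rich in heterochromatin, was covered to 13.1% ± 0.81 with 57 regions in replicate 1 and 55 in replicate 2. It stood within the range of the large arms in replicate 1 (13.7%), whereas its 12.6% in replicate 2 was below that of each large arm. In the higher-scoring 50% of each list chromosome 4 was covered to 8.60% in replicate 1, within the 7.30% to 9.60% of the large arms, and to 2.48% in replicate 2, below their 8.39% to 11.3%. Heterochromatic and unplaced scaffolds carried few regions: the 6 Het sequences and U together were covered to 0.98% ± 0.05, with 76 regions in replicate 1 and 72 in replicate 2. XHet (6.00% ± 0.28) and YHet (3.76% ± 0.03) had the highest shares among them, from 4 and 6 regions in each replicate, and U the lowest (0.56% ± 0.06). The share of these scaffolds to which reads can be assigned uniquely was not measured. The Y-linked scaffold appeared in both lists, in embryos whose sex the labels do not give.

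**Figure D2:**
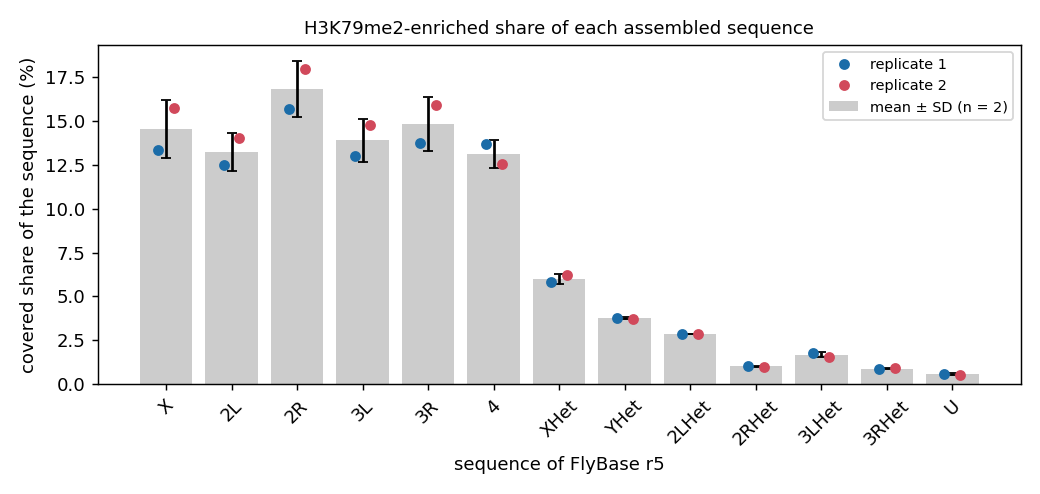
Share of each FlyBase release 5 sequence covered by H3K79me2-enriched regions (bars, mean; error bars, SD, n = 2; points, single replicates). The large arms and chromosome 4 lie between 12.5% and 18.0%, and the Het and U scaffolds at 6.19% or lower.

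X was compared with the autosomal arms, since the male X is subject to dosage compensation in flies. X was covered to 13.4% in replicate 1 and 15.7% in replicate 2, and the autosomal arms to 13.7% and 15.6%. The difference of X minus autosomes was -0.31 percentage points in replicate 1 (95% bootstrap interval -1.92 to 1.76) and 0.11 in replicate 2 (-1.92 to 2.45), so no difference was detectable. In the higher-scoring 50% of each list it was 0.15 (-1.18 to 1.80) and 1.05 (-0.59 to 3.01), again with intervals that include 0. Regions on X scored higher by 0.08 in replicate 1 (-0.07 to 0.20) and by 0.13 in replicate 2 (0.03 to 0.26), of which the interval excluded 0 in replicate 2 only. Median width on X was larger by 39 bp in replicate 1 (-27 to 175) and by 112.5 bp in replicate 2 (-35 to 298).

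Coverage was low at the centromere end of 4 of the 5 large arms as assembled. Here the 1 Mb next to the centromere means the assembled 1 Mb at that end of the arm. The Het sequences were kept apart from it, and the distance from there to the centromere itself was not measured. The 1 Mb next to the centromere was covered to 1.80% ± 0.46 on 3L, 5.20% ± 0.27 on 2R, 5.99% ± 0.35 on X and 6.22% ± 0.52 on 2L (SD, n = 2). The arms between their end stretches were covered to 14.2% ± 1.22 on 3L, 17.4% ± 1.67 on 2R, 14.9% ± 1.73 on X and 13.3% ± 1.04 on 2L. On these 4 arms the centromere end was lower in both replicates. The share of these ends to which reads can be assigned uniquely was not measured either. A lack of the mark there was therefore not separated from a lack of readable sequence. Arm 3R did not show the drop, with 15.9% ± 1.86 in its first assembled 1 Mb against 14.9% ± 1.54 between its ends. The separate 3RHet sequence was covered to 0.87% ± 0.03 (SD, n = 2), so the absence of a drop holds for the assembled arm only. The 1 Mb next to the telomere was covered to 17.1% ± 2.07 over the 5 arms, against 14.9% ± 1.44 between the ends. The rise lay mainly on 2L (19.2% ± 2.42 against 13.3%) and 3L (19.5% ± 2.74 against 14.2%). X (15.5% ± 1.59 against 14.9%) and 2R (18.1% ± 1.91 against 17.4%) were only slightly higher at this end, in both replicates. Replicate 1 gave 14.3% against 13.7% on X and 16.7% against 16.2% on 2R. Replicate 2 gave 16.6% against 16.2% on X and 19.4% against 18.5% on 2R. Arm 3R was lower at this end (13.2% ± 1.68). The most densely marked whole 1-Mb bins began at 10 Mb on 2L (25.1% ± 0.55), 19 Mb on 2R (24.5% ± 1.79) and 5 Mb on 3R (23.9% ± 2.77). Low bins also occurred inside the arms, at 14 Mb (4.54% ± 0.73) and 17 Mb (5.10% ± 0.43) of 2L and at 10 Mb of 3L (5.75% ± 0.54).

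**Figure D3:**
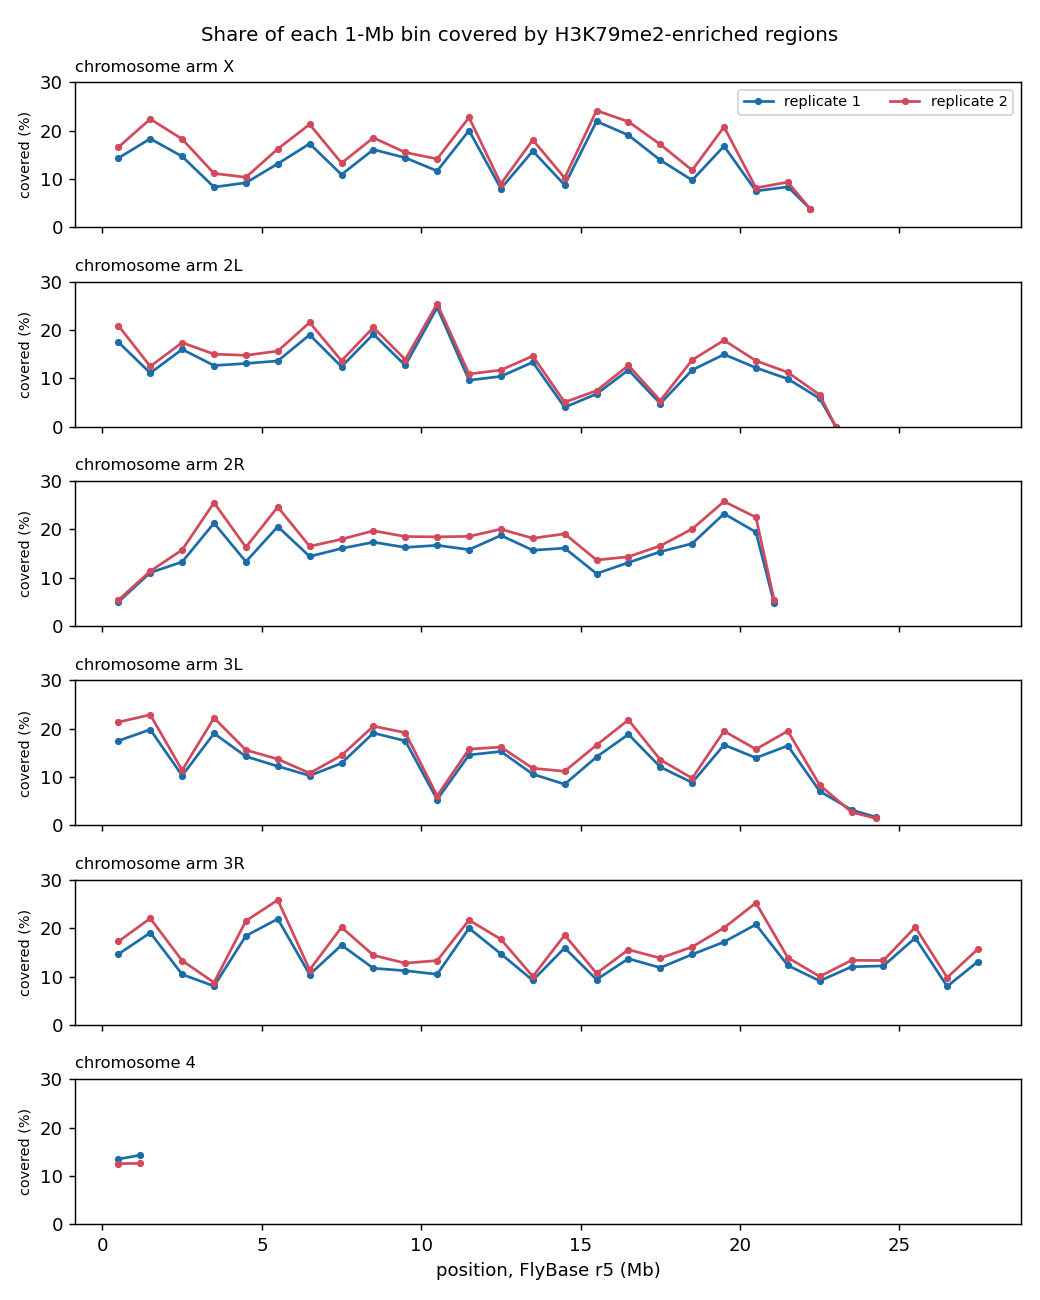
Share of each 1-Mb bin covered by H3K79me2-enriched regions (y axis, percent) along the large arms and chromosome 4 (x axis, FlyBase release 5 position in Mb; the last bin of each is shorter) for replicate 1 and replicate 2. Both replicates follow the same course, with maxima near 25% and a drop at the centromere end, right on X, 2L and 3L and left on 2R, but not on 3R. The shorter last bin of 2R, at its telomere end, is also low (mean 5.01%). That of 2L (0%) spans only 23000001 to 23011544.

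Enriched regions were clustered, with long stretches left without any. On the 5 large arms, the median distance between neighbouring regions was 7403 bp in replicate 1 and 6975 bp in replicate 2. Random placement of the same regions gave 14291 bp ± 210 and 14010 bp ± 216 (SD over 1000 placements), and no placement reached the observed values (one-sided permutation p = 0.001, the smallest possible). Distances under 5 kb made up 40.6% of all in replicate 1 and 41.8% in replicate 2, against 21.6% and 21.9% at random. Distances over 100 kb numbered 208 and 213, against 41.9 ± 5.66 and 38.3 ± 5.55 at random. The random placements took no account of where genes lie or where reads can be assigned uniquely. They therefore cannot tell clustering of the mark from uneven spacing of genes or of readable sequence. Merging regions less than 500 bp apart raised the mean of the 2 medians from 7189 to 8407 bp.

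The longest stretches free of regions in both replicates lay on 2L from 15771978 to 16165308 (393 kb) and from 16911068 to 17258581 (348 kb), and on X from 21502117 to 21845607 (343 kb), the last within the assembled 1 Mb at the centromere end. A stretch of 303 kb on 3L from 24226094 to 24529515 and one of 288 kb from 23732736 to 24020729 also lay at the centromere end of the assembled arm. A 281 kb stretch on 2L from 14690090 to 14970725, a 278 kb stretch on 2R from 15719977 to 15998180 and a 274 kb stretch on 3R from 23876638 to 24150395 lay inside the arms. In all, 195 stretches of over 100 kb without a region in either replicate made up 24.4% of the 5 large arms. How much of these stretches can take uniquely assigned reads was not measured.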

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

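The list for the replicate set held 2 regions called depleted, which enter none of the comparisons above. Both lay on 2L, from 9539952 to 9541682 with a score of -0.01 and from 22967786 to 22969412 with a score of -0.08. All 1731 bp of the first lay inside a region that replicate 1 listed as enriched, and none of it in replicate 2. Of the second, 1544 of 1627 bp lay inside an enriched region of replicate 2, and none in replicate 1.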

How the results depend on the processing

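The alternatives for the centromere ends, the distance between neighbours, the correlation of scores and the excess of the score difference on chromosome 4, the Het sequences and U were chosen after the results had been seen. Taking the higher-scoring 50% of each list left 2538 regions by construction and moved the covered share to 7.81%, the median width to 3768 bp, the median distance between neighbours to 12133 bp, and the covered share next to the centromere to 4.14%, of chromosome 4 to 5.54% and of the Het sequences and U to 0.43%. X minus autosomal arms became 0.60 percentage points against -0.10, and the Spearman correlation of replicate scores 0.48, over a narrower range of scores. The 5 large arms alone gave a covered share of 14.6%, since the sparse scaffolds drop out, and a Spearman correlation of 0.865 against 0.856. Merging neighbours less than 500 bp apart gave a median distance of 8407 bp. The list for the replicate set gave 7.63% next to the centromere, 14.7% for chromosome 4 and 1.18% for the Het sequences and U. The covered share next to the centromere was 9.04% with 2 Mb in place of 1 Mb. The list for the replicate set held 64 regions on chromosome 4, against 57 in replicate 1 and 55 in replicate 2. On the Het sequences and U it held 90, against 76 and 72. Why it held more regions there, and why coverage was higher further from the centromere end, was not tested. The other 63 alternative values stayed within 1 SD of the replicates (for the number of regions, within 1.5 times; for the correlation, within its 95% interval) or on the same side of their threshold, although the excess of the score difference on chromosome 4, the Het sequences and U fell from 0.70 to 0.21 with the higher-scoring 50%, a choice that removes regions scoring low in replicate 2 and so lowers this difference by construction. A minimum width of 1000 bp removed no region and so tests nothing. Leaving out either replicate tests nothing either, since with 2 replicates each value lies within 1 SD of their mean. X minus autosomal arms, the share next to the centromere and the distance between neighbours were computed on the 5 large arms anyway. Restricting to these arms therefore could not change them. All these empty alternatives are counted among the 63. The overlap test passed in all its alternatives (one-sided permutation p = 0.005, the smallest that 200 shifts can give), but the share of replicate 2 regions counted as shared fell to 74.3% when 80% of the length had to be covered. Depth is not given, so the limit it sets on low-scoring regions cannot be stated. No paired analysis was possible because the input samples have no values here and only 1 group remains. The alternatives of the analyses that need a release 5 annotation, and a fit with replicate as a block, were not run.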

Other observations

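The spacing by score, the difference in scores on chromosome 4, the Het sequences and U with all its tests, and the difference in widths were chosen after the results had been seen, as were the widths by sequence and the comparison of edges within regions, but not the other 2 tests of the widths. In both replicates high-scoring regions lay closer to other regions than low-scoring ones. Parts of a domain that a list holds as several regions count as neighbours here. The distances by score were not repeated with neighbours merged or at equal width. Over all sequences, regions scoring 2 or more had a median width of 3462 bp in replicate 1 and 4146 bp in replicate 2. For regions scoring under 1 it was 2037 and 2090.5 bp, so score and width were not told apart. On the 5 large arms, regions scoring 2 or more had a median distance to the nearest other region of 2.39 kb in replicate 1 (95% bootstrap interval 2.23 to 2.52) and 2.11 kb in replicate 2 (1.93 to 2.28). Regions scoring under 1 stood 5.41 kb (4.86 to 5.87) and 4.67 kb (4.24 to 5.21) from the nearest. Regions on the Het sequences and U had a median score close to that of the large arms in replicate 1 (2.21 against 2.19) and a lower one in replicate 2 (1.39 against 1.89). Of the regions on the Het sequences and U that both replicates covered, the highest replicate-set score was 3.43, on U from 7542004 to 7544888. That region scored 3.56 in replicate 1 and 3.27 in replicate 2. Another on U, from 6383828 to 6386638, scored 3.42 in the replicate set, 3.83 in replicate 1 and 2.57 in replicate 2.

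Paired regions on chromosome 4, the Het sequences and U scored higher in replicate 1 by a median of 0.83 (85 of 101 regions higher), against 0.20 on the large arms without their centromere ends. This was 0.70 above 10000 random arm sets matched on mean score and width, beyond all of them, which argues against score level or width as the cause (0.21 with the higher-scoring 50% of each list, a choice that removes regions scoring low in replicate 2). The 101 paired regions of all 5 centromere ends exceeded matched sets by 0.19, above 99.99% of them but unevenly (2L 0.48, 2R 0.98, 3L 1.12, X 0.01, 3R 0.06), and chromosome 4 alone by 0.77, which argues against mapping to the Het and U scaffolds as the whole cause. A constant offset of these sequences in the ChIP or the input of one replicate stays open: the excess was 0.78 over the 50 regions with the higher and 0.54 over the 51 with the lower mean scores, a difference of 0.25 with a 95% interval of -0.07 to 0.52. Since each replicate had its own input and no reads were used here, ChIP and input were not separated, and neither mapping to repeats in general nor any biological explanation was tested.

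Regions found in 1 replicate only were narrower than the others, with median widths of 1912 against 2891 bp in replicate 1 and 1856 against 3318 bp in replicate 2. The list for the replicate set overlapped, by any length, 91.3% of the 253 such regions of replicate 1 and 70.7% of the 420 of replicate 2. Why they lacked a partner was not tested.

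Paired regions on the large arms were wider in replicate 2 (median 306 bp, 95% interval 294 to 317), but not those on chromosome 4 (-159 bp, -196.5 to 11, 40 regions) or on the Het sequences and U (-21 bp, -111 to 47.6, 61 regions). Joining of neighbours was tested as the cause. All regions paired one to one, which cannot have been joined with another listed region, were still wider by a median of 299.5 bp, so joining was not the whole cause. The left edge lay further out in replicate 2 by a median of 143 bp (95% interval 136 to 151) and the right edge by 138 bp (131 to 145). Within regions, however, both edges did so in 48.3% of pairs and 1 edge in 47.3%. Across pairs, the extensions of the left and the right edge had a Spearman correlation of -0.17 and a Pearson correlation of -0.08. The noise of single called edges was not measured.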
